A study of Homo sapiens with 54 samples.

How the data were processed

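RNA sequencing libraries were made from 54 samples of U2OS cells, grouped by their titles into 9 groups of siRNA arm and RNA fraction with 6 times each. The library whose title and treatment label disagreed was kept under its title. Reads were processed with Trim Galore, Bowtie2 and RSEM 1.3.0 on the hg19 genome build, per the submitters' processing notes, which give no order or parameters. The deposited table gives one value per RefSeq transcript and column, in TPM, transcript abundance scaled to a fixed sum per library, by its name. TPM values from the authors' files are relative to the other transcripts of a library and keep no read depth.

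All 54 columns of values in the deposited table were left unused. Each column name, and each of the 3 experiment codes, was compared with every label of the series after removing punctuation and case, and 0 of 54 names and 0 of 3 codes were found. Assigning columns by their order, by their serial numbers or by the values in them was ruled out, because an error there would change which siRNA, fraction or time a value stands for. The tests set out before the data were examined (limma on log2 values for level, slope and enrichment, exact permutation tests for gene classes, and gene list tests) were not run.

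Only the header and the transcript accessions were read, with Python 3.11.15. Accessions without versions were matched to a RefSeq gene table of assembly GRCh38, used for names only, and 3318 of 52000 had no match there. The 21 gene lists, fixed before the data were examined, hold 899 memberships, and a gene may be in several lists. List members were matched by current symbol, or by an older symbol that belongs to a single gene. Of the 899 memberships, 872 were matched to a transcript in the table.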

Results

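The study followed RNA turnover in U2OS, an established human osteosarcoma cell line. It asked how N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, and the m6A-binding protein YTHDF2 bear on the rate at which transcripts are lost. Cells received a control siRNA or 1 of 2 siRNAs against YTHDF2. Cytoplasmic RNA was then collected at 0, 0.5, 1, 2, 4 and 6 h. At each time, the RNA was sequenced as total input, as the m6A immunoprecipitate and as the flow-through, which holds the RNA that the antibody left behind. The 3 siRNA arms, 3 RNA fractions and 6 times made 54 libraries, with 1 library for each combination. The labels name no agent that stopped transcription. For 1 library, the total input titled as the first YTHDF2 siRNA at 6 h, the title and the treatment label named different siRNAs.

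The deposited expression table had 54 columns of values. Their names combined 3 experiment codes, each on 18 columns, with a serial number. Of the 54 column names, 0 appeared in any label of the libraries, and 0 named an siRNA arm or an RNA fraction. No column was therefore given to a library, and 0 of the 54 columns were used. Levels, enrichment over flow-through and slopes over time are not analysed here, for YTHDF2 as for other genes. None of the comparisons between the YTHDF2 siRNAs and the control siRNA, between immunoprecipitate and flow-through, or between time points was made. The efficiency of the YTHDF2 knockdown was not checked, and the sequencing depth is unknown.

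The row names show which transcripts the table covers. It lists 52000 RefSeq transcripts, of which 39880 are protein-coding (NM) and 12120 are non-coding (NR) accessions. A current annotation named 48682 of them, or 93.6%, and these belong to 25657 genes. Of these genes, 15810 have 1 named transcript in the table and 9847 have more than 1. The other 3318 transcripts were not given to a gene, so the number of transcripts given for a gene is a minimum. YTHDF2 has 3 named transcripts, and its paralogs YTHDF1 and YTHDF3 have 1 and 8. METTL3 and METTL14, the core of the m6A methyltransferase complex, have 1 each. SON has 5 transcripts, CREBBP has 2 and MYC has 1.

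All 21 listed m6A writers, erasers and readers have at least 1 transcript in the table, as do 27 of 30 deadenylation, decapping and exonuclease factors. The 50 immediate early and other short-lived regulators are all covered, and so are 99 of 100 KRAB-type zinc finger genes and 49 of 50 large chromatin regulators. A row was also matched for 75 of 78 cytosolic ribosomal proteins, 72 of 73 nuclear-encoded oxidative phosphorylation genes and 51 of 52 replication-dependent histones. For nuclear-retained RNAs, 16 of 18 were matched. Every member of the lists not named in this paragraph was matched. Of 15 mitochondrially encoded genes, 0 were matched to a row. Whether these genes have NM or NR accessions, the only kinds in the table, was not checked. A gene with neither kind could have no row, so the 0 may be a real absence from the table. The reason for the 0 was not determined. These counts rest only on the transcripts that the current annotation named. A member without a match may still be among the 3318 unnamed transcripts, if it has an NM or NR accession. The counts say nothing about expression.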

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

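None of the alternatives planned before the data were examined was run, because no column of values was given to a library. Both alternatives below were chosen after seeing the data. Counting only protein-coding (NM) accessions lowered the number of genes with a transcript in the table from 25657 to 18716. Matching list members by current symbol only lowered the memberships covered from 872 to 871. No paired analysis was possible because no column name was tied to the label of a library, although the design itself would allow pairing by time.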
